A study of Mus musculus with 5 samples.

How the data were processed

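Gene expression was measured on 5 microarrays hybridised with biotin-labelled RNA from neural stem cells of the adult mouse subventricular zone, a germinal layer lining the lateral ventricles. Per the labels, 3 arrays held cells in which Notch2 had been deleted with a tamoxifen-inducible Cre driven by Hes5 (Notch2 cKO), and 2 held wild-type controls. The mice were 8 to 10 weeks old and received tamoxifen for 5 days at postnatal day 56. The tissue was dissected and dissociated with papain, and per the series description recombined cells were sorted. Replicate numbers only name the arrays and pair none of them. The array titles end in 2 dates. The first date held control 1 and Notch2 cKO 2, and the second held control 2, Notch2 cKO 1 and Notch2 cKO 3. The labels do not state that each array came from a separate animal, so p-values measure the spread between these samples.

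The deposited intensity values were on a linear scale, per the file headers, with 1 value per probe set and array. The array design was the mouse whole-transcript gene array named by the platform annotation. Background correction, summarisation and normalization by the authors are not given in the sources used here. The values of the 5 arrays lay on a common scale, with array medians between 24.3 and 24.9 intensity units. The same intensities stood in both deposited tables for all 35556 probe sets, so no separate alternative was run on the second table. The second table also held a fold change, a linear ratio made by the authors, which was empty for 5379 probe sets. How that ratio was made was worked out from the values. For 30176 of 30177 probe sets it equalled, within 0.001 on the log2 scale, the geometric mean of the 3 Notch2 cKO arrays over control 2 alone. The mean of both controls gave a match for 100 probe sets (0.331%).

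Intensities were converted to log2 with no pseudocount and no further normalization. Of the probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 were unnamed in it. Symbols were updated through the Entrez identifier, which matched for 21698 probe sets, with the gene table of assembly GRCm38.p6. Only probe sets with 1 symbol were tested. For the 999 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 19938 genes with no filter on brightness. Signal over background was judged from 1242 olfactory, vomeronasal and taste receptor genes, which were taken as mostly silent in this tissue. The 95th percentile of their means, 5.59 on the log2 scale or 48.1 intensity units, served as a reference level. This reference was chosen after seeing the data.

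Differences between Notch2 cKO and control were fitted with limma (lmFit, and eBayes with an intensity trend) with the date as a fixed term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit left 2 residual degrees of freedom per gene, and moderation raised this to 8.04. Gene lists were tested with camera on the same design with an intensity trend, a preset correlation between genes of 0.01 and adjustment over 29 lists. The lists held 837 entries, of which 768 were measured. They covered Notch signalling, stem and progenitor states, cell cycle, neural and other cell types, stress, metabolism, ribosomal proteins and sex-linked genes. The design, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took Notch2, then up to 12 rises and 12 falls past the threshold with every Notch2 cKO array on the same side of the control of its own date. Where fewer passed, places went to the smallest unadjusted p under that condition. Uncharacterised features and olfactory or vomeronasal receptor genes were not named. Each list added up to 4 members with the largest change in the direction of its median, of which the text gives a part.

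Alternatives were no date term, the date as a random block, the second date alone, quantile normalization, median centring, 2 filters on dim genes, eBayes without trend or robust, array weights, the mean of a gene's probe sets, each array left out, no moderation, other thresholds, camera with an estimated correlation, and the rotation test fry. For lists, the random block and the robust fit were tested on the moderated statistics with cameraPR. A filter at the receptor level and fry after median centring were added after seeing the data.

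The fit was tested on simulated data for Notch2 cKO against control, with the fitted means of the 19938 genes and 200 genes changed. Variances were drawn from the distribution that the moderation fitted, so the simulated data followed the model. Recovery was thus measured under the model's own assumptions, with 200 genes changed at once. At an adjusted p under 0.05, limma recovered 0 of 200 genes changed 2-fold, 186 changed 4-fold, 199 changed 8-fold and 198 changed 16-fold. False calls numbered 0, 8, 12 and 8. A shift of 0.5 on the log2 scale placed in the ribosomal protein list was called by camera, with 0 other lists called among 29. Simulated genes were independent, which real genes are not. The number of arrays limits the precision. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe sets with several symbols or none were left out of the gene tests.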

Results

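The data were 5 arrays of neural stem cells sorted from the adult mouse subventricular zone, 2 from controls and 3 from Notch2 cKO mice. Signal was low on all of them. Of 18696 genes other than olfactory, vomeronasal and taste receptor genes, 2370 (12.7%) had a mean above the 95th percentile of those receptor genes, 5.59 on the log2 scale. On single arrays the share above that array's own percentile was 6.20% for control 1 and 5.15% for control 2. It was 16.7% for Notch2 cKO 1, 7.66% for Notch2 cKO 2 and 11.5% for Notch2 cKO 3. The percentile itself stood at 5.93, 6.08, 5.56, 5.86 and 5.74 in the same order. Hes5, the Notch target whose promoter drove the Cre, lay above the reference level at 6.75 ± 0.23 in controls (SD, n = 2) and 6.77 ± 0.08 in Notch2 cKO (SD, n = 3). Gfap, an astrocyte and stem cell filament gene, lay below it at 4.91 ± 0.01 and 4.84 ± 0.05. Across genes, Pearson's r between arrays ran from 0.812, between the 2 controls, to 0.890, between Notch2 cKO 1 and Notch2 cKO 2. For genes with a mean above the reference level it ran from 0.504 to 0.725. Genes are not independent replicates.

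The deleted gene was read first. Notch2, a receptor of the Notch pathway (probe set 10494595), measured 4.81 ± 0.09 in controls (SD, n = 2) and 4.89 ± 0.22 in Notch2 cKO (SD, n = 3), below the receptor reference level in both. The change was 0.04 on the log2 scale with a standard error of 0.20, a 95% interval from -0.43 to 0.51 and an adjusted p of 0.982 in limma. A gene-level value may hold probes outside the deleted part, so it checks neither the deletion nor the labels.

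The comparison of Notch2 cKO with control asked which transcripts differ after conditional loss of Notch2. No gene passed. Among the named genes with the smallest p-values, Vdac3, a mitochondrial outer membrane channel, measured 5.63 ± 0.23 in controls (SD, n = 2) and 3.70 ± 0.25 in Notch2 cKO (SD, n = 3). Rps4x, a ribosomal protein gene, measured 8.25 ± 0.72 and 5.74 ± 0.43. COX2, here the mitochondrially encoded cytochrome c oxidase subunit, measured 10.64 ± 1.81 and 5.90 ± 2.92. In the other direction Fabp7, a radial glia fatty acid binding protein, measured 3.65 ± 0.25 and 4.77 ± 0.05, and Gpx2, a glutathione peroxidase, measured 4.19 ± 0.06 and 5.56 ± 0.35.

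In limma 0 of 19938 genes had an adjusted p under 0.05 and 0 under 0.1, with a smallest adjusted p of 0.240. At an unadjusted p under 0.05 there were 1325 genes, 696 higher and 629 lower, where 996.9 are expected by chance. Whether 1325 exceeds the spread of that number among correlated genes was not tested. Every Notch2 cKO array lay on the same side of its own date's control for 7370 genes (37.0%), and chance gives 33.3%. Receptor genes fell under that p in 158 of 1242 cases (12.7%) and other genes in 1167 of 18696 (6.24%). With the second date alone limma called 66 genes, all lower in Notch2 cKO, and control 2 was the highest of the 5 arrays for 64 of them. Leaving out 1 array gave 65 genes without control 1, 65 without Notch2 cKO 2, 7 without control 2, 6 without Notch2 cKO 3 and 0 without Notch2 cKO 1. For a single gene, leaving out control 2 left the first date's change, and leaving out control 1 or Notch2 cKO 2 left the second date's.

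The 12 higher genes chosen by the rule did not pass. Log2 changes with standard errors were 1.27 ± 0.20 for Fhl3, 1.31 ± 0.21 for Gpx2, 1.15 ± 0.21 for Fabp7, 1.27 ± 0.24 for Gabrb2, a GABA-A receptor subunit, and 1.12 ± 0.23 for Uap1l1, which was 0.72 without control 2. The other 7 were Btnl10, F2rl3, Espl1, which encodes separase, Wdr83os, Chrna10, Klk1b9 and an immunoglobulin kappa variable gene, with changes from 0.92 for Espl1 to 1.08 for the immunoglobulin gene. Of the 12, Fhl3 alone had a mean above the receptor reference level, and all 12 had a control mean below it.

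The 12 lower genes did not pass either. Log2 changes with standard errors were -4.08 ± 0.56 for COX2, -3.28 ± 0.59 for Hspe1, a mitochondrial chaperonin, -2.74 ± 0.40 for Igha, -2.53 ± 0.38 for Rps4x and -1.95 ± 0.24 for Vdac3. Cyp4a12a, Zhx1, Atp5h, Psmd10, Mrps33, S100a11 and Hspd1, the partner chaperonin of Hspe1, had changes from -1.25 for Psmd10 to -1.56 for S100a11. Of the 12, 10 had a Notch2 cKO mean below the receptor reference level, among them Hspe1 at 4.42, Igha at 4.95 and Vdac3, so the sizes of their changes rest on values near background. The means of COX2 and Rps4x lay above it. COX2 stood at 9.26 on Notch2 cKO 2 but at 3.93 on Notch2 cKO 1 and 4.53 on Notch2 cKO 3. The size of its second-date change thus also rests on values near background. Rps4x stood at 5.89, 6.08 and 5.26 on Notch2 cKO 1, Notch2 cKO 2 and Notch2 cKO 3. By date the changes were -1.49 and -4.62 for Hspe1, -1.67 and -3.55 for Igha, -2.67 and -5.14 for COX2, and -1.67 and -3.18 for Rps4x. COX2, Igha, Rps4x and Hspe1 passed limma's threshold with the second date alone, where a single control array stood for the group. Vdac3 passed it without Notch2 cKO 3, with an adjusted p of 0.0314 in limma. Signal of COX2, Rps4x and others of these genes, such as Hspd1 and S100a11, may include near-identical copies elsewhere in the genome, which was not checked.

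**Figure D1:**
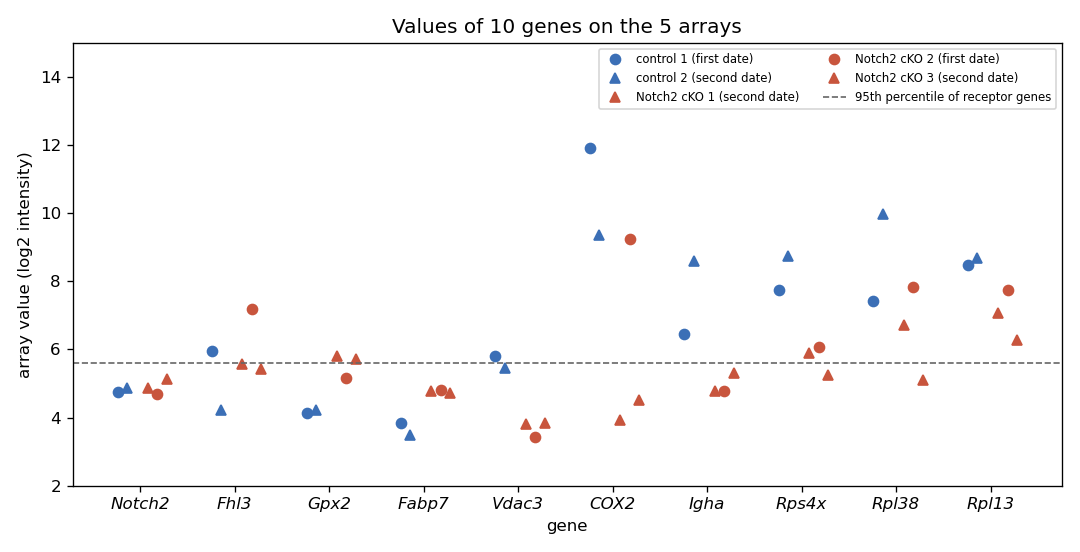
Log2 intensity (vertical axis) of 10 named genes (horizontal axis) on each array, with controls in blue, Notch2 cKO in red, circles for the first date, triangles for the second, and a dashed line at the receptor reference level of 5.59. Notch2 lay between 4.68 and 5.12 on all arrays, and COX2 ran from 3.93 on Notch2 cKO 1 to 11.92 on control 1.

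Ribosomal protein genes were the list that passed in camera. Of 32 measured members, 22 lay above the receptor reference level, 22 had a negative and 10 a positive log2 change, and the median change was -0.43. For the 22 above that level it was -0.19, and with genes above it alone the list had an adjusted p of 0.00101 in camera. No member passed over all genes, and 8 passed when adjusted over the list alone. Rpl38 measured 8.69 ± 1.81 in controls (SD, n = 2) and 6.55 ± 1.38 in Notch2 cKO (SD, n = 3), Rpl13 measured 8.58 ± 0.14 and 7.03 ± 0.74, and Rps13 measured 6.48 ± 1.15 and 4.92 ± 0.45. Rpl38 stood at 9.97 on control 2, with a change of 0.43 on the first date and -4.06 on the second, and without control 2 its change was 0.43 (-1.41 without Notch2 cKO 3). Rps13 had changes of -2.87 and -0.49 by date and Rpl13 -0.74 and -2.01. The list fell in camera with an adjusted p of 4.4e-06. With an estimated correlation between genes of 0.171, camera gave an adjusted p = 0.859.

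The median change of ribosomal protein genes was -1.0 on the first date, with 28 of 32 lower, and 0.056 on the second, with 15 of 32 lower and a mean of -0.12. Array medians of the list were 7.04 for control 1, 5.38 for control 2, 6.0 for Notch2 cKO 1, 6.01 for Notch2 cKO 2 and 5.38 for Notch2 cKO 3. Without control 1 camera gave an adjusted p of 0.795, and without Notch2 cKO 2 it gave 0.798.

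**Figure D2:**
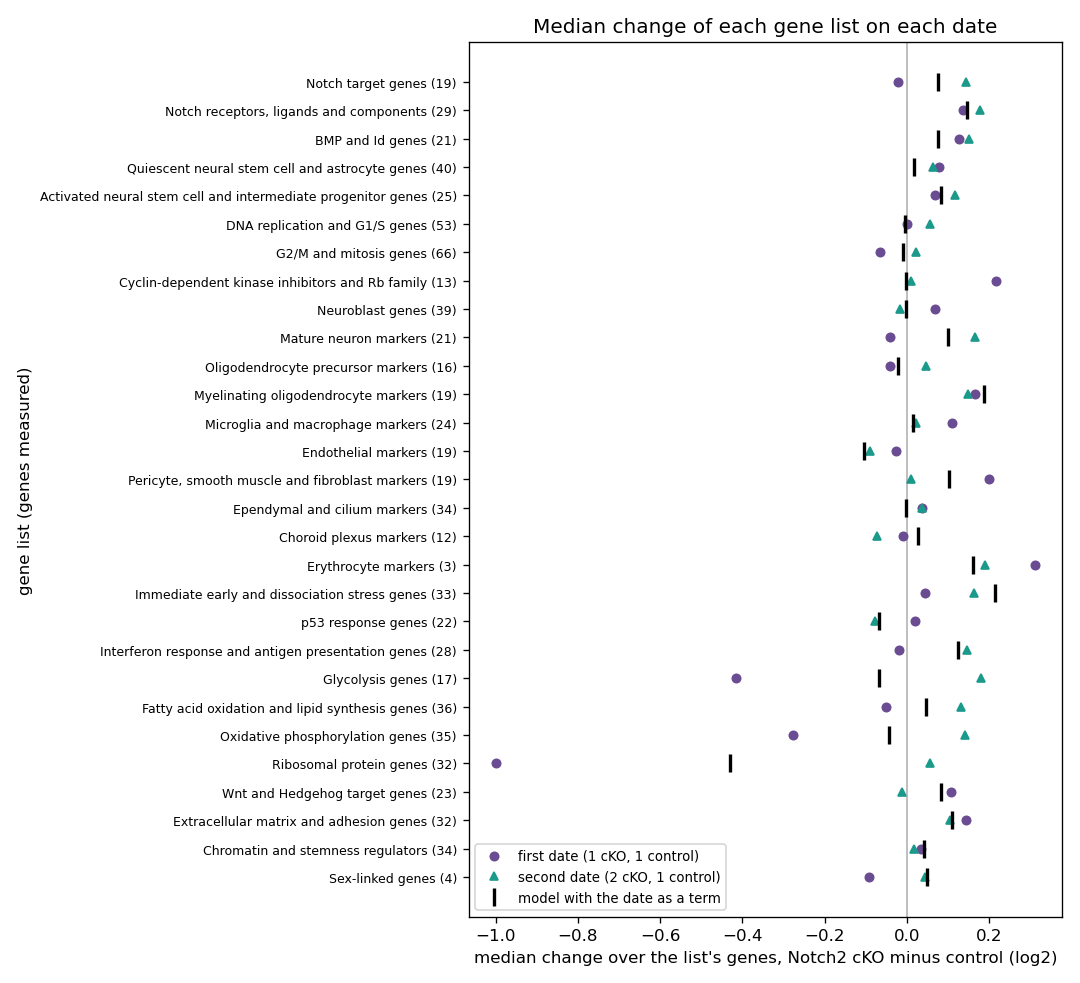
Median log2 change, Notch2 cKO minus control (horizontal axis), of each of 29 gene lists (vertical axis, genes measured in parentheses) on the first date (circles), on the second date (triangles) and in the model with the date as a term (bars). Ribosomal protein genes lay at -1.0 on the first date and 0.056 on the second.

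Notch pathway lists did not pass camera. The 19 Notch target genes had a median change of 0.08 and an adjusted p of 0.679 in camera, with Nrarp at 0.67 ± 0.25 (SE) and Hes1 at 0.47 ± 0.26, both below the receptor reference level. By date the changes were 1.04 and 0.39 for Nrarp (0.39 without control 1) and -0.07 and 0.88 for Hes1 (-0.07 without control 2). The 6 targets above the reference level had a median change of -0.05. Fabp7 alone passed when adjusted over the list alone, in this list and among progenitor genes. The 29 Notch receptors, ligands and components had a median of 0.15 and an adjusted p of 0.615 in camera, with Notch1 at 0.45 ± 0.19. In fry, which asks whether the members move one way, this list had an adjusted p of 0.0077 and mature neuron markers 0.032, both upward. After median centring of the arrays both had an adjusted p of 0.142 in fry. The 21 BMP and Id genes had a median of 0.08 (camera, adjusted p of 0.679).

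Stem cell, progenitor and cell cycle lists did not pass camera. Median changes were 0.02 for 40 quiescent stem cell and astrocyte genes (adjusted p of 0.946 in camera), 0.08 for 25 activated stem cell and intermediate progenitor genes (0.679) and 0.00 for 39 neuroblast genes (0.679). Among these, Ntsr2 had a change of 0.51 ± 0.22 (SE), Egfr 0.46 ± 0.25 and Tubb3 -0.66 ± 0.22. By date the changes were 0.81 and 0.29 for Ntsr2 (0.29 without control 1) and 0.23 and 0.63 for Egfr (0.23 without control 2 and 0.29 without Notch2 cKO 3). Medians were 0.00 for 53 DNA replication genes (adjusted p of 0.740 in camera), -0.01 for 66 mitosis genes (0.592) and 0.00 for 13 cyclin-dependent kinase inhibitor and Rb family genes (0.939). Nek2 had a change of -0.75 ± 0.24, Pcna -1.08 ± 0.59 and Cdkn1b -0.93 ± 0.45. Among DNA replication genes 2 rose and 1 fell at an unadjusted p under 0.05 in limma. Tk1, the brightest of that list, had a change of 0.78 ± 0.28. Pcna stood at 6.74 and Cdkn1b at 7.69 on control 1, and without that array or Notch2 cKO 2 their changes were 0.27 and 0.06, and without control 2 they were -2.88 and -2.26. For 34 chromatin and stemness regulators the median was 0.04 (0.946), with Sox1 at 0.44 ± 0.20.

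Markers of other cell types gave no call in camera. Median changes were 0.10 for mature neuron markers (adjusted p of 0.628 in camera), -0.02 for oligodendrocyte precursors (0.740), 0.19 for myelinating oligodendrocytes (0.679) and 0.01 for microglia and macrophages (0.939). They were -0.10 for endothelial markers (0.592), 0.10 for pericyte, smooth muscle and fibroblast markers (0.946), 0.00 for ependymal and cilium markers (0.679), 0.03 for choroid plexus markers (0.946) and 0.16 for erythrocyte markers (0.679). Cfap43, a cilium gene, had a change of -1.88 ± 0.67 (SE), with control 2 at 9.76 and the other arrays between 5.95 and 6.50, and without control 2 its change was 0.14. Without control 1 or without Notch2 cKO 2, which leaves the second date alone, it was -3.40 with an adjusted p of 0.0187 or 0.0203 in limma. Sex-linked genes had a median of 0.05 (0.739), and all 4 lay below the receptor reference level. Kdm5d, at -0.74 ± 0.23 (-0.46 and -0.95 by date), passed when adjusted over that list alone.

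Stress, metabolic and other lists gave no call in camera with all 5 arrays. Median changes were 0.21 for immediate early and dissociation stress genes (adjusted p of 0.679 in camera) and -0.07 for p53 response genes (0.592). They were 0.12 for interferon response and antigen presentation genes (0.966) and -0.07 for glycolysis genes (0.679), the last with -0.41 and 0.18 by date. They were 0.05 for fatty acid oxidation and lipid synthesis genes (0.946), -0.04 for oxidative phosphorylation genes (0.592), 0.08 for Wnt and Hedgehog targets (0.817) and 0.11 for extracellular matrix and adhesion genes (0.939). Oxidative phosphorylation genes passed lower in camera without control 2 (median -0.28, adjusted p of 0.000197) and without Notch2 cKO 1 (-0.08, 0.0329). Without control 1 or Notch2 cKO 2 their median was 0.14 (0.808 and 0.812). B2m, the light chain of class I antigen presentation, had a change of -1.40 ± 0.29 (SE) and passed when adjusted over its list alone, with -0.89 and -1.77 by date. Cycs, which encodes cytochrome c, had a change of -1.34 ± 0.31, and Hk1, a hexokinase, had -0.71 ± 0.22. Cycs was at -0.64 on the first date and -1.86 on the second, and at -0.64 without control 2. In 5 lists the median or mean and the direction in camera differed in sign: microglia and macrophages, choroid plexus, fatty acid oxidation and lipid synthesis, chromatin and stemness regulators, and sex-linked genes.

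The 2 dates were compared with genotype in the model. No gene passed in limma, with a smallest adjusted p of 0.057. Rps28, a ribosomal protein gene, measured 8.56 and 8.43 on the first date's arrays and between 5.73 and 6.25 on the second date's. At an unadjusted p under 0.05 there were 1868 genes, and 9 had an adjusted p under 0.1 in limma. Ribosomal protein genes fell from the first to the second date, with a median of -0.38 and an adjusted p of 6.5e-06 in camera. The list's array medians were 7.04 for control 1 and 6.01 for Notch2 cKO 2 on the first date. On the second they were 5.38 for control 2, 6.0 for Notch2 cKO 1 and 5.38 for Notch2 cKO 3. Control 1 was thus the only array well above the rest. With an estimated correlation this list had an adjusted p = 0.861. Leaving out 1 array gave 55 genes past limma's threshold without Notch2 cKO 2, 35 without Notch2 cKO 3, 18 without control 1, 17 without control 2 and 0 without Notch2 cKO 1.

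In the authors' deposited table, Rps4x stood at a fold of 0.124, Vdac3 at 0.293, Fabp7 at 2.16 and Notch2 at 1.01. Of the 30177 probe sets with a fold in the authors' deposited table, 596 were at least 2-fold higher and 1221 were at 0.5-fold or less. Those folds set the 3 Notch2 cKO arrays against control 2 alone. Control 2 was on the second date and control 1 on the first, while the Notch2 cKO arrays came from both. Folds against either control therefore mix date with genotype, which the fit separates. Against control 1, 450 were at least 2-fold higher and 2128 at 0.5-fold or less, among them 103 of the 596 (17.3%) and 493 of the 1221 (40.4%). Both comparisons share all 3 Notch2 cKO arrays, and 100 simulated sets with no effect and no date difference gave overlaps of up to 27.9% and 29.3%. Those sets treated both controls and both directions alike, while the counts here differ between controls and directions. They therefore do not show whether 40.4% exceeds what shared arrays give. Across genes, Pearson's r between the authors' deposited table and the fitted changes was 0.848, and 100 simulated sets with no effect on the same arrays gave a mean of 0.846. The covariance was 0.129 and the simulated covariance 0.0849.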

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

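The tests of explanations in this part were chosen after the results were seen. A term for genotype and date together passed in camera for 2 lists. Its adjusted p was 0.000291 for ribosomal protein genes, with medians of -1.0 and 0.056, and 0.00078 for oxidative phosphorylation genes, with medians of -0.28 and 0.14. With an estimated correlation both had an adjusted p of 0.976. Of the 4 groups by genotype and date 3 held 1 array, so Notch2 cKO 1 and Notch2 cKO 3 gave all the spread between arrays, and a difference between the dates is not established. The same term passed for 10 genes in limma, with a smallest adjusted p of 0.0149, and 1275 genes lay under an unadjusted p of 0.05. Across 19938 genes the changes on the 2 dates had a Pearson's r of 0.068, and 52.5% had the same sign; genes are not independent replicates.

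Lower ribosomal protein genes in Notch2 cKO may rest on control 1, since without that array camera gave an adjusted p of 0.795. Leaving out Notch2 cKO 2 also ended the call (0.798), because either omission leaves the second date alone. A shift of all genes of like brightness was argued against. Of 10000 random lists matched on brightness, 0% had a median as low as -0.43, and the bounds of their medians were -0.02 and 0.21. Those lists drew genes independently, and the ribosomal list was chosen after it had passed. The 0% is therefore not a p-value for the list. On the second date the list showed no fall in its median, at 0.056, with 15 of 32 genes lower and 17 higher. The standard error of 0.34 over genes treats genes as independent and measures no spread between arrays. With a single control array on that date, a genotype difference present on both dates was neither shown nor excluded.

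At an unadjusted p under 0.05 there were 1325 genes for genotype in limma, against 996.9 expected by chance. Correlated genes widen the spread of such a count, so an excess was not established. On the same arrays the date gave 1868 genes and the term for genotype and date together 1275. For genotype, the share under that p was 2.04 times as high among receptor genes, which lie near background, as among other genes. Variation of the background level between arrays may therefore account for part of the 1325 genes. A genotype difference in some of these genes was not tested apart from it.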

How the results depend on the processing

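Signal near background limits results for most genes. The count of genes changed between Notch2 cKO and control stayed at 0 in limma except with the second date alone (66), with each array left out (0 to 65), and at an unadjusted p under 0.05 with at least 1.5-fold (854). Where an omission left a group with 1 array on a date, that array was assumed to vary like the rest. Without control 1 there were 65 genes, without control 2 7, without Notch2 cKO 2 65 and without Notch2 cKO 3 6. The count between the 2 dates moved from 0 to 8 with median centring, 9 with robust eBayes, 9 at an adjusted p under 0.1 and 1306 at the unadjusted p with 1.5-fold, and from 0 to 55 with each array left out. Notch2 stayed uncalled throughout. The number of lists past the threshold was 1, and became 0 with the second date alone, 0 with an estimated correlation, 2 with fry, 0 with fry after median centring, and 0 to 2 with each array left out, where oxidative phosphorylation genes were added without control 2 and without Notch2 cKO 1. For ribosomal protein genes the adjusted p was 0.799 with the second date alone, 0.859 with an estimated correlation, 0.553 with fry and 0.701 with fry after median centring, and ran from 1.2e-12 to 0.798 with each array left out. The second date alone and the omissions used fewer arrays and also changed how much each date counted. The median of ribosomal protein genes was -1.0 without control 2 and 0.056 without control 1, with the same number of arrays. The number of arrays alone therefore does not account for the moves. The fry values above ask whether members move one way. Fry's test for change in either direction gave an adjusted p of 0.0358 for Notch target genes. It gave 0.0438 for ribosomal protein genes, activated stem cell and intermediate progenitor genes, and myelinating oligodendrocyte and microglia and macrophage markers. Fry does not compare a list with other genes. For the rest the cause was not tested. Of 2211 values of 134 other named genes, 2194 kept their side of the threshold, 17 newly passed it and 59 changed sign. Limiting the test to genes above the receptor level and fry after median centring were chosen after seeing the data.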

Other observations

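The tests in this part were chosen after seeing the data. Mitochondrially encoded transcripts, were read from 25 probe sets that the deposited table names only for mitochondrial genes, 1 of which was among the genes tested. Their median was 10.50 on control 1, 8.74 on control 2, 4.90 on Notch2 cKO 1, 9.32 on Notch2 cKO 2 and 4.82 on Notch2 cKO 3 (log2). All 25 were lower in Notch2 cKO on the first date and 24 on the second. As a set they had a p of 1.4e-17 in camera, and p = 0.023 with an estimated correlation. No probe set passed over all 35556 in limma, and 10 passed when adjusted over the set alone. Among 2243 gene ontology terms, camera called 1, the small ribosomal subunit, lower with an adjusted p of 0.0101. With an estimated correlation its unadjusted p in camera was 0.057. The term was read on the same arrays as the ribosomal protein list and was not split by date. It is therefore no separate support for a ribosomal fall.

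For the lower mitochondrially encoded transcripts, a single array was argued against as the whole cause, since the median change was -1.46 or lower with each array left out. The medians of -1.46 on the first date and -2.36 on the second go with a genotype difference present on both dates. On the first date a single array stood against a single control, and Notch2 cKO 2 at 9.32 lay above control 2 at 8.74. On the second the Notch2 cKO medians, 4.90 and 4.82, lay below the receptor reference level. The size of -2.36 therefore rests on values near background. Less cellular RNA on the Notch2 cKO arrays stays open. The share of genes above an array's own receptor percentile goes against it, but rests on genes near background on 5 arrays. The share was 16.7%, 7.66% and 11.5% on Notch2 cKO and 6.20% and 5.15% on controls. That percentile was itself lower on Notch2 cKO, at 5.56, 5.86 and 5.74, than on controls, at 5.93 and 6.08. The 40 Gapdh probe sets had a median change of -0.058, but the deposited values were already on a common scale.

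Control 2 had 26 genes at least 3 log2 units above all other arrays, and the other arrays had 4 to 6 each.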
